A study of Mus musculus with 12 samples.

How the data were processed

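CircRNA sequencing was carried out on 4 mouse cell lines with 3 libraries each: 4T1 (breast cancer cells), Eph4-ev (breast epithelial cells), B16F10 (melanoma cells) and Melan-a (melanocytes). Per the labels' protocols, total RNA was treated with RNase R, an exonuclease that digests linear RNA. Adapters were then joined to both ends, and the RNA was reverse-transcribed and amplified. CircRNAs were detected with CIRI2 (on BWA-MEM alignments) and CIRCexplorer2 (on TopHat and TopHat-Fusion alignments). The build is mm10, per the submitters' processing notes, which also name DESeq, DESeq2 and edgeR without a role. How the reads of the callers were combined, which filters were applied and which annotation was used are not given in the sources used here.

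There is 1 table per lineage. The count columns hold raw back-spliced junction reads per circRNA and library, per the file headers. The RPM columns, per the file headers, hold RPM: by their values, the authors scaled each count by the total of its column. RPM times the column total was a whole number within 0.01 for 100% of values, and the recovered reads differed from the deposited counts by at most 0. The count test was therefore used throughout, and RPM values describe levels. The total is that of the junction reads in the table, so RPM says nothing of the amount of circular RNA per cell. The mammary table lists 9492 circRNAs, all with reads. The melanocyte table lists 12910, of which 4053 have 0 reads in all 6 libraries and 8857 have reads. Both list 8928, and 5519 have reads in both. The number of per-sample columns without a sample in the labels was 0.

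Coordinates are 1-based on mm10, as deposited. Exon numbers and regions come from GENCODE M21: 99.2% of starts and 99.3% of ends of the circRNAs in the mammary table lie at annotated exon boundaries, with a median of 3 exons. Host genes are those the tables name. Host values are counts summed over all circRNAs with a single host, which leaves out 160 rows of the mammary and 201 of the melanocyte table. The labels mention no molecular identifiers, so reads may not be independent molecules, and intervals and floors cover counting error only.

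Each lineage was tested alone with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr with a minimum count of 5 and a minimum total of 10, Benjamini-Hochberg adjustment) in R 4.3.3, and a difference was called at an adjusted p under 0.05. Fold changes are tumour line minus non-tumour line on the log2 scale, with SE from the F statistic. A circRNA counted as found only in 1 line when it had at least 2 reads in each of that line's 3 libraries and 0 in each of the others. For these, the fold is a bound against a floor of 3 counts over the 3 libraries of the line at 0. With 1 to 3 counts in a line, the pooled ratio is given with its 95% exact counting interval. Bounds and pooled ratios are scaled by total junction reads without TMM factors, so they are not on the same scale as the log2 folds. The difference between lineages was tested with edgeR as the interaction over all 12 libraries, on circRNAs that both tables list. Overlap of calls was tested with Fisher's exact test (two-sided). Gene lists were tested at host level with limma 3.58.1 camera (preset correlation 0.01, prior count of 2, lists with at least 3 tested members). Single values per library were compared with exact two-sided permutation tests, whose smallest p with 3 against 3 is 0.1.

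The designs, the 12 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Per comparison, the rule named the 5 most abundant circRNAs of each line. It named the 4 with the largest called fold in each direction, among those with at least 5 reads on average in both lines, and the 5 most abundant called circRNAs found only in each line. It also named up to 3 tested hosts of each list with the smallest p. Of circRNAs called in both comparisons, it named the 4 in each direction whose larger p was smallest. Some genes that this rule names are not reported here. The lists hold melanocyte and pigment genes, epithelial genes, mesenchymal and fibroblast genes, immune cell genes, keratinocyte genes, chromatin regulators, cell cycle genes, DNA repair genes, growth factor and MAPK/PI3K signalling genes, TGF-beta and BMP signalling genes, antigen presentation and interferon genes, and hosts of well described circRNAs. Older symbols in the tables were matched (Inadl for Patj, Whsc1 for Nsd2).

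Alternatives were RLE factors, scaling by total reads alone, no filter, a minimum count of 10, DESeq2 1.42.0, replicate number as a block, an added fold threshold, other detection minimums, thinning of line-only and detected circRNAs to equal depth, fry and estimated correlations for the lists, and leaving out each library. Thinning before the tests, limma-voom with quality weights and the host-level interaction were chosen after seeing the data. On simulated counts with known changes, 25.5% of 4-fold and 68.5% of 8-fold changes were recovered in the mammary circRNA test over 1825 rows, and 72.7% and 96.2% in the melanocyte circRNA test over 821 rows. In the test of the difference between lineages over 1190 rows, 9.26% of 4-fold and 22.4% of 8-fold differences were recovered. The simulated counts gave all rows the common dispersion of their fit. They left out the losses of circRNAs from single libraries seen in the data, so recovery in the data may differ. Python 3.11.15 with scipy 1.17.1 and numpy 2.4.6 was used for the other tests.

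Every pair of libraries of 1 line differed by more than sampling noise (chi-square per degree of freedom 1.69 to 5.06), so they were not summed as repeat reads of 1 library. This does not show that they are biological replicates. Over circRNAs with reads in either library of a pair, most of them at few reads, ranks agreed weakly. Spearman correlations were 0.081 to 0.116 in 4T1, 0.300 to 0.307 in Eph4-ev, 0.146 to 0.165 in B16F10 and 0.134 to 0.147 in Melan-a. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.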

Results

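Back-spliced junction reads, which span the join that closes a circular RNA, were counted in 4T1 and Eph4-ev and in B16F10 and Melan-a, with 3 libraries per line. The series title asks for circRNAs specific to tumours, so each tumour line was compared with the non-tumour line of its lineage. Each lineage has 1 line of each kind, so tumour state cannot be told apart from other differences between the lines. Depth was low and uneven. The 4T1 libraries, from breast cancer cells, held 15572, 17735 and 44625 junction reads and the Eph4-ev libraries, from breast epithelial cells, 50648, 56649 and 55549. The B16F10 libraries, from melanoma cells, held 20011, 16943 and 16697 and the Melan-a libraries, from melanocytes, 25072, 33557 and 25157. A single read thus stands for 64.2 RPM in 4T1 replicate 1.

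A 4T1 library held 3324 ± 299 circRNAs with at least 1 read (SD, n = 3) and an Eph4-ev library 5171 ± 291 (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 allows). Thinned to 15572 reads each, the 4T1 libraries held 3170, 3017 and 3052 circRNAs and the Eph4-ev libraries 3617, 3735 and 3519 (exact permutation p = 0.1). A B16F10 library held 3735 ± 269 (SD, n = 3) and a Melan-a library 3677 ± 499 (SD, n = 3; exact permutation p = 0.8). The difference, B16F10 minus Melan-a, turned negative with at least 2 reads (-421). It did so too without B16F10 replicate 1 (-97.8) and without Melan-a replicates 1 (-62.3) and 3 (-110). Thinned to 16697 reads each, the B16F10 libraries held 3778, 3555 and 3583 and the Melan-a libraries 3097, 3453 and 3016 (exact permutation p = 0.1).

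**Figure D1:**
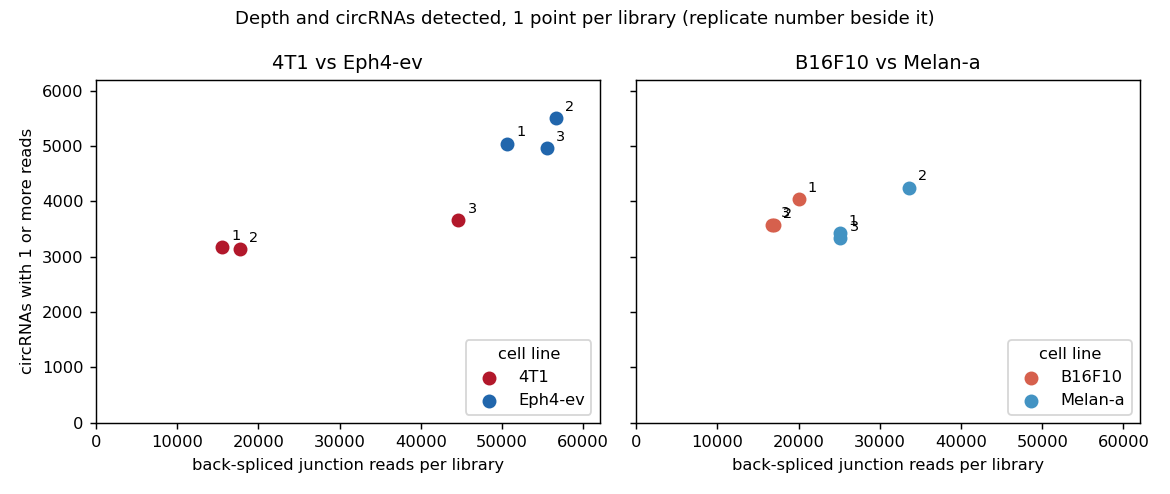
Number of circRNAs with 1 or more reads (y axis) against back-spliced junction reads (x axis), 1 point per library with its replicate number, for the mammary lines (left) and the melanocyte lines (right). The 3 Eph4-ev libraries, at 50648 to 56649 reads, lie above the 3 4T1 libraries in detected circRNAs, and 4T1 replicate 3 has 3669 at 44625 reads.

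In 4T1 against Eph4-ev, circRNAs of Nfix and Pvt1 were among the 5 most abundant of both lines. That of Nfix, a transcription factor gene (chromosome 8, 84771784 to 84772315, exon 2), stood at 17749 ± 1724 RPM in 4T1 and 11992 ± 765 in Eph4-ev (SD, n = 3). Its log2 fold was 0.33 (SE 0.12, edgeR adjusted p = 0.0814), and it passed under limma-voom (adjusted p = 0.0103), total-read scaling (0.0139), a minimum count of 10 (0.0246) and thinning (0.045). That of the long noncoding gene Pvt1 (chromosome 15, 62107148 to 62107465, exon 2) stood at 17612 ± 2002 and 14099 ± 1759 RPM (SD, n = 3; edgeR adjusted p = 0.732). Those of Gigyf2 (chromosome 1, 87364104 to 87380008, exons 4 to 8) and Tns3 (chromosome 11, 8518199 to 8519570, exons 14 to 16) did not pass the test either (adjusted p = 0.604 and 0.383). Among the abundant ones, that of Med13l, a subunit of the Mediator kinase module (chromosome 5, 118593333 to 118593570, exon 2), was higher in 4T1 by 1.61 (SE 0.18, adjusted p = 0.000321). Those of Dtnb, Vapa and Ptbp3 were lower, with log2 folds of -2.44 (SE 0.18), -2.49 (SE 0.17) and -3.15 (SE 0.29).

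Among the largest called folds of circRNAs with reads in both lines was that of the RNA-binding protein gene Qk (chromosome 17, 10273947 to 10282981, exons 2 to 3). It had 24, 43 and 67 reads in 4T1 and 12, 4 and 11 in Eph4-ev (log2 fold 3.18, SE 0.45, edgeR adjusted p = 0.00151). Others higher were those of Cers6, a ceramide synthase, at 2.92 (SE 0.58), and Adk, adenosine kinase, at 2.92 (SE 0.45). In the other direction, the circRNA of exon 2 of Zfp609 (chromosome 9, 65794622 to 65795495) had 14, 17 and 46 reads in 4T1 and 332, 392 and 397 in Eph4-ev (log2 fold -3.03, SE 0.19, adjusted p = 8.16e-06). That of the spindle checkpoint gene Bub1b (chromosome 2, 118631759 to 118635277) had 15, 0 and 0 reads against 139, 110 and 130 (log2 fold -3.55, SE 0.89). That of Snx12 (chromosome X, 101213774 to 101215578) had 0, 0 and 19 against 49, 105 and 99 (log2 fold -3.06, SE 0.74). This pair rested on uneven 4T1 libraries, and DESeq2 gave adjusted p of 0.358 for Bub1b and 0.111 for Snx12. Without Eph4-ev replicate 2 the edgeR values were 0.0949 and 0.101, with 0.0694 for Cers6.

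Some circRNAs had reads in 1 line alone. By the rule of 2 reads in each library, 52 were found only in 4T1 and 334 only in Eph4-ev, and edgeR called 40 of the 40 and 92 of the 95 it could test. The rule had already selected these on the same counts, so the share called follows largely from it and is no separate support. The most abundant only in 4T1 came from Fam160b1 (chromosome 19, 57378549 to 57379175; 25, 51 and 106 reads; at least 124-fold higher) and Kirrel3os (chromosome 9, 34983621 to 34985144, with no matching exons in 1 transcript; at least 101-fold). Next came Mtcl1 (chromosome 17, 66436080 to 66438391; at least 71.8-fold higher), the ubiquitin ligase gene Nedd4 (chromosome 9, 72669952 to 72686114; at least 66.6-fold) and the kinase gene Stk39 (chromosome 2, 68307041 to 68314603; at least 58.5-fold). Those only in Eph4-ev included circRNAs of Rad23b (chromosome 4, 55366777 to 55370472; at least 26.5-fold lower in 4T1), Zfpm2 (at least 25.4-fold) and Tacc2 (at least 18.1-fold). Because the Eph4-ev libraries are deeper, the counts of such circRNAs are not like for like: thinned to equal depth they were 68 and 93. Without 1 library, which leaves fewer libraries to meet the rule, they were 62 to 128 and 447 to 598. With a minimum of 1 read in place of 2 they were 96 and 549, and with 5 reads 16 and 119.

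**Figure D2:**
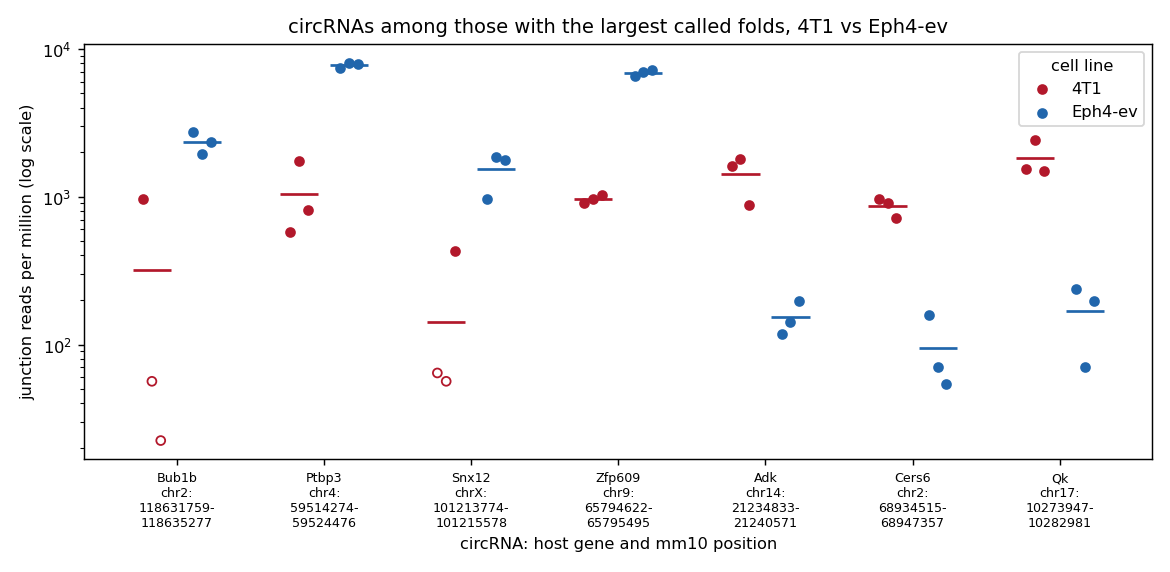
RPM (y axis, log scale) of circRNAs among those with the largest called folds between 4T1 and Eph4-ev and reads in both lines (x axis: host gene and mm10 position), with filled points for libraries, bars for the mean of 3 libraries and open circles for libraries with 0 reads, drawn at the level of 1 read. Zfp609 is tight in both lines, while Bub1b and Snx12 have 2 4T1 libraries at 0 each.

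Over the 1869 circRNAs tested, edgeR called 112 higher and 213 lower in 4T1. Summed over their circRNAs, 104 of 1515 host genes were higher and 161 lower. The balance depends on the scaling: with total reads alone the circRNA counts were 142 and 176, and the median log2 fold of all tested circRNAs moved from -0.22 to -0.01. With no filter 72 were higher, and thinned to equal depth 109 were lower, with 97 host genes lower. Without 1 library, the circRNAs higher were 67 (4T1 replicate 1), 54 (4T1 replicate 3), 55, 30 and 46 (Eph4-ev replicates 1, 2 and 3), and those lower 112, 42 and 97 (Eph4-ev replicates 1, 2 and 3). The host genes higher were 63 without 4T1 replicate 3 and 61, 31 and 52 without Eph4-ev replicates 1, 2 and 3, and those lower 96, 42 and 90 without these Eph4-ev replicates.

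Among the gene lists, 4 of the 24 tested chromatin regulators were lower in 4T1 and 2 higher. Ezh2, the catalytic subunit of Polycomb repressive complex 2, had a log2 fold of -1.98 (SE 0.22, edgeR adjusted p = 1.56e-05), Asxl2 of -1.75 (SE 0.30) and Whsc1 of -0.93 (SE 0.25). Named after their values were seen, Arid1a was also lower, Eed and Kdm6a were higher, and each of these 3 lost its call without most single libraries. Of the 20 tested growth factor and MAPK/PI3K signalling genes 4 were lower and 0 higher by edgeR, and 5 lower and 0 higher by DESeq2 and by limma-voom (8 at an unadjusted p under 0.05). Among the edgeR calls were the receptor gene Fgfr2 (0 reads in 4T1 against 78, 55 and 55; at least 30.3-fold lower) and, named after its value was seen, Met (log2 fold -2.36, SE 0.68). Of 9 TGF-beta and BMP signalling genes 2 were lower, Smad4 (log2 fold -2.28, SE 0.61) and Smad3 (0 reads against 9, 11 and 10; at least 4.78-fold lower). Bmpr2 did not pass (log2 fold 3.27, SE 1.25, adjusted p = 0.0864; limma-voom 0.0313). Of 8 epithelial genes 2 were lower, the polarity gene Inadl (log2 fold -2.47, SE 0.47) and the motor gene Myo5b (log2 fold -2.38, SE 0.47), and Magi1 did not pass (adjusted p = 0.081). Without Eph4-ev replicate 2 adjusted p was 0.0528 for Inadl, 0.0614 for Myo5b, 0.135 for Whsc1, 0.139 for Met, 0.169 for Smad4 and 0.136 for Smad3. Calls were also lost for Whsc1 without Eph4-ev replicate 1 (0.0533), Met without Eph4-ev replicates 1 (0.112) and 3 (0.0528), and Smad4 without 4T1 replicate 3 (0.0661). That of Smad3 was lost without 4T1 replicates 2 (0.0503) and 3 (0.0813) and Eph4-ev replicates 1 (0.0968) and 3 (0.0934), and with the replicate block (0.122).

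Cell cycle genes went both ways, with Bub1b lower (log2 fold -2.96, SE 0.54), the polymerase subunit Pole2 higher (log2 fold 2.92, SE 0.96, edgeR adjusted p = 0.0465) and Ect2 not called (adjusted p = 0.128), among 12 tested. Of 25 tested hosts of well described circRNAs 3 were higher and 4 lower, among them Qk (log2 fold 2.68, SE 0.32), Zfp609 (log2 fold -2.97, SE 0.20) and Asph (log2 fold -1.49, SE 0.23). The 7 tested DNA repair genes gave 0 calls by edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p under 0.05 (Trp53bp1 adjusted p = 0.0898, Rev3l 0.18). Of the 3 melanocyte and pigment genes tested, Ap3b1, which is also expressed outside pigment cells, was lower (log2 fold -2.03, SE 0.68, adjusted p = 0.0497). Hps5 and Myo5a were not called (adjusted p = 0.54 and 0.898). Of the mesenchymal list only Zeb1 was tested (0 reads against 6, 10 and 7; adjusted p = 0.0528), with 0 calls by edgeR, DESeq2 or limma-voom and 1 at an unadjusted p under 0.05. Of the antigen presentation list only Canx and Pdia3 were tested (adjusted p = 0.305 and 0.811), with 0 calls by edgeR, DESeq2 or limma-voom and 0 at an unadjusted p under 0.05. Of the immune and keratinocyte lists 0 members had reads. Adjusted over the list alone, 5 chromatin regulators were lower and 3 higher, 6 signalling genes, 3 epithelial genes and 2 TGF-beta genes were lower, and 5 hosts of well described circRNAs were lower and 3 higher. The cell cycle list gave 1 lower and 1 higher so, Ap3b1 and Zeb1 were lower and the DNA repair and antigen presentation lists gave 0. Bub1b was not called without Eph4-ev replicate 2 (0.061). Pole2 was lost without any 1 library (0.0679 to 0.179), with no filter (0.0929) and with the replicate block (0.0836). Ap3b1 was lost without any 1 library but 4T1 replicate 3 (0.0847 to 0.238), under total-read scaling (0.0629) and under thinning (0.0908). Rev3l passed without 4T1 replicate 1 (0.0321).

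As a set, 0 of the 8 lists with enough members passed limma camera (0 at an unadjusted p under 0.05; lowest 0.0594, growth factor and MAPK/PI3K signalling), and 0 with an estimated correlation (lowest adjusted p 0.824). That list passed without 4T1 replicate 3 (adjusted p = 0.0177). The fry test, which asks whether members move one way on balance, gave an adjusted p of 0.0484 each for the epithelial and the signalling lists (down) and the cell cycle list (up). Log2 folds were positive for 4 of 8 epithelial, 6 of 20 signalling and 8 of 12 cell cycle genes. Unlike camera, fry does not set a list against the other hosts. For chromatin regulators the median (-0.08), mean (-0.28) and fry were negative where camera pointed up. For the TGF-beta list the median was 0.25 and the mean -0.57, with camera and fry pointing down. For hosts of well described circRNAs they were 0.07 and -0.33, with camera pointing up and fry down. With hosts at 0 reads set to their bounds, the list medians were as given except for Zeb1 alone (-1.87). The means were not taken again so. They keep the fitted folds of such hosts, among them Smad3 (-5.95) in the TGF-beta list.

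In B16F10 against Melan-a, circRNAs of the receptor tyrosine kinase genes Met and Epha3 were higher and those of Zfp609, Vps45, Slc7a11 and Gbe1 lower. The circRNA of exons 2 to 3 of Met (chromosome 6, 17487797 to 17492437, across the start of the coding sequence) had 125, 120 and 133 reads in B16F10 and 7, 44 and 10 in Melan-a (log2 fold 3.28, SE 0.46, edgeR adjusted p = 0.000291). That of exons 2 to 4 (17487797 to 17513541) had a log2 fold of 3.38 (SE 0.36). The circRNAs of Epha3 had log2 folds of 2.92 (SE 0.44; chromosome 16, 63772910 to 63773570) and 2.51 (SE 0.44; 63652215 to 63653578). The circRNA of exon 2 of Zfp609 had 3, 9 and 9 reads against 135, 89 and 133 (log2 fold -3.52, SE 0.44, adjusted p = 0.000107). That of Vps45 (chromosome 3, 96041338 to 96042928) had a log2 fold of -3.87 (SE 0.43) and that of the glycogen branching enzyme gene Gbe1 of -2.05 (SE 0.36). That of Slc7a11, the cystine transporter gene (chromosome 3, 50417988 to 50438915), had 7, 6 and 8 reads in B16F10 and 141, 11 and 173 in Melan-a (log2 fold -3.46, SE 0.77, adjusted p = 0.00993). Its call was lost without B16F10 replicate 1 (adjusted p = 0.0788), Melan-a replicate 1 (0.0839) or Melan-a replicate 3 (0.0642).

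Of the most abundant circRNAs, that of Elf2 (chromosome 3, 51308050 to 51326035) stood at 20162 ± 1682 RPM in B16F10 and 25292 ± 3595 in Melan-a (SD, n = 3; edgeR adjusted p = 0.226). Those of Gigyf2 and Pvt1 were lower, with log2 folds of -0.93 (SE 0.21, adjusted p = 0.0123) and -0.89 (SE 0.20, adjusted p = 0.0121). Both were lost without any 1 of the B16F10 libraries (adjusted p between 0.0815 and 0.14), and that of Gigyf2 also without Melan-a replicate 3 (0.0661). That of Pvt1 did not pass with no filter (0.076) or the replicate block (0.0506) either. Those of the selenocysteine elongation factor gene Eefsec (log2 fold 1.23, SE 0.23) and of the circRNA with hosts Eif5b and Rev1 (chromosome 1, 38053616 to 38085652; log2 fold 1.66, SE 0.28) were higher. That of Phf21a (chromosome 2, 92214049 to 92230724) was among the 5 most abundant of Melan-a yet had 358, 607 and 0 reads there and 289, 0 and 0 in B16F10. It did not pass (adjusted p = 0.677) except with no filter (0.00269) and without B16F10 replicate 1 (0.0356). A circRNA of the collagen gene Col28a1 (chromosome 6, 8127284 to 8158174, exons 9 to 13) had 335, 452 and 354 reads in Melan-a and 0 in B16F10 (at least 244-fold lower).

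By the rule of 2 reads in each library, 33 circRNAs were found only in B16F10 and 44 only in Melan-a (45 and 24 at equal depth). Of those that could be tested, edgeR called 8 of 10 and 7 of 7, a share that again follows largely from selection on the same counts. Without 1 library the counts were 48 to 92 and 72 to 135. Those only in B16F10 included 2 of Fto, an RNA demethylase gene (chromosome 8, 91401807 to 91522896, 28, 24 and 27 reads, at least 41.3-fold higher, and 91401807 to 91485278, at least 29.5-fold). The others named were circRNAs of Akap7 (at least 27.8-fold), Inpp5f (at least 19.3-fold) and Cntln (at least 12.8-fold), the last lost without B16F10 replicate 1 (adjusted p = 0.14) and under limma-voom (0.0601). Those only in Melan-a included, besides Col28a1, circRNAs of the mRNA capping enzyme gene Rngtt (at least 38.2-fold lower in B16F10), Vps45 (at least 16.4-fold), Zfp609 (chromosome 9, 65730976 to 65795495; at least 12.6-fold) and Agap1 (at least 12.3-fold).

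**Figure D3:**
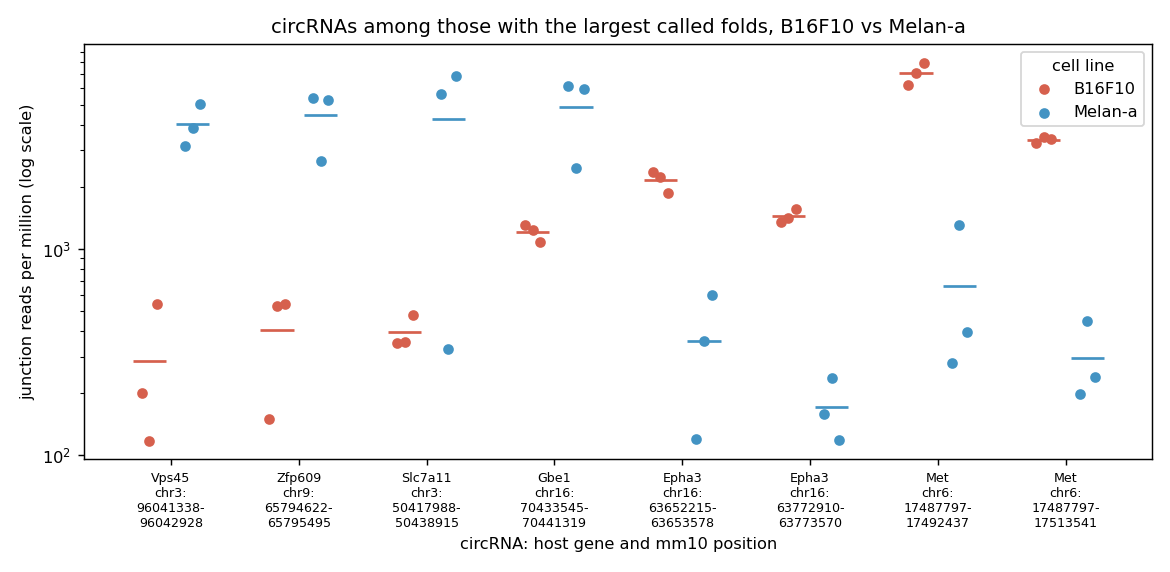
RPM (y axis, log scale) of circRNAs among those with the largest called folds between B16F10 and Melan-a and reads in both lines (x axis: host gene and mm10 position), with points for libraries and bars for the mean of 3 libraries. For Slc7a11, 1 Melan-a library (11 reads) lies near the B16F10 libraries, far from the other Melan-a libraries (141 and 173 reads).

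Over the 874 circRNAs tested, edgeR called 44 higher and 51 lower in B16F10, and over 898 host genes 25 higher and 39 lower. The balance depends on the scaling. With total reads alone, 55 circRNAs were higher and 47 lower, and 36 and 32 host genes. Under RLE factors these counts were 45 and 55 circRNAs and 33 and 38 host genes. The filter matters as well: with none, 34 circRNAs were higher and 35 lower, and 41 and 41 host genes. Melan-a replicate 2 weighs on these counts: without it edgeR called 72 circRNAs higher and 73 lower, and 60 and 63 host genes. Without B16F10 replicates 1, 2 and 3 and Melan-a replicates 1 and 3, in this order, circRNAs higher were 22, 27, 22, 26 and 25, circRNAs lower 20, 26, 23, 26 and 28, host genes higher 19, 16, 16, 19 and 19, and host genes lower 13, 16, 17, 17 and 17.

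In the lists, 1 of 17 tested growth factor and MAPK/PI3K signalling genes was higher, Met (log2 fold 3.28, SE 0.41, edgeR adjusted p = 0.000287), and 1 lower, the Ras GTPase activator Rasa2 (log2 fold -0.995, SE 0.24). Of 21 chromatin regulators Ash1l, a histone methyltransferase, was higher (log2 fold 1.502, SE 0.26). The SWI/SNF subunits Arid1a (0, 1 and 0 reads against 23, 24 and 30; 49.3-fold lower, 95% counting interval 8.59 to 1972) and Arid1b (log2 fold -1.30, SE 0.31) were lower. Of 24 hosts of well described circRNAs 2 were higher, Tulp4 (log2 fold 1.93, SE 0.35) and, named after its value was seen, Fbxw7 (log2 fold 1.23, SE 0.33). Zfp609 (log2 fold -3.77, SE 0.39) and Pvt1 (log2 fold -0.93, SE 0.19) were lower. Without B16F10 replicates 1, 2 and 3, adjusted p was 0.166, 0.129 and 0.0572 for Arid1b, 0.186, 0.112 and 0.139 for Rasa2, and 0.181, 0.107 and 0.0796 for Fbxw7, and without replicates 1 and 3 it was 0.0917 and 0.0769 for Pvt1. Without Melan-a replicate 1 it was 0.0798 for Rasa2, 0.108 for Fbxw7 and 0.0605 for Pvt1. Without Melan-a replicate 3 it was 0.0664 for Arid1b, 0.0901 for Fbxw7 and 0.0664 for Pvt1. Arid1b did not pass under thinning either (0.0665).

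The 10 tested melanocyte and pigment genes gave 0 edgeR calls over all hosts (2 at an unadjusted p under 0.05), against 2 higher by DESeq2 and 1 by limma-voom. Adjusted over the list alone, 2 were higher. For Pax3, a transcription factor gene of the melanocyte lineage, B16F10 had 15, 18 and 18 reads and Melan-a 3, 14 and 1 (log2 fold 2.10, SE 0.63, adjusted p over all hosts = 0.0591). For Pmel, which encodes the amyloid protein of melanosomes, they had 201, 140 and 147 against 112, 214 and 87 (log2 fold 0.82, SE 0.26, adjusted p over all hosts = 0.0702). Both lie at the threshold: over all hosts they passed with RLE factors (0.0494 each), total-read scaling (0.0446 and 0.0436), no filter (0.0116 and 0.0295), a minimum count of 10 (0.0482 and 0.0484), DESeq2 (0.0355 and 0.0135) and the replicate block (0.0111 and 0.0477). Pax3 alone passed under thinning (0.0457) and Pmel alone under limma-voom (0.00702). Without Melan-a replicate 2 both passed as well (adjusted p = 0.00407 and 0.00149), as did Bub1b (0.000387) and Cdh2 (0.0402), which otherwise did not (0.188 and 0.455). Bub1b also passed with no filter (0.0319), with the replicate block (0.0315) and under limma-voom (0.0134). Trpm1 was not called (adjusted p = 0.254).

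The other lists in B16F10 gave 0 edgeR calls and 0 DESeq2 calls. DESeq2 gave no adjusted p for 244 of the 898 host genes here and 59 of the 1515 in 4T1, so it could not call these. At an unadjusted p under 0.05 were 1 of 4 cell cycle genes (Bub1b; Pola1 adjusted p = 0.373, Cep192 0.405) and 1 of 4 DNA repair genes (Xrcc4 0.062, Trp53bp1 0.39, Prkdc 0.833). At that level were 0 of 2 TGF-beta genes (Acvr2a 0.76, Smad4 0.787) and 0 of the single members tested of the epithelial (Pard3 0.732), mesenchymal (Cdh2 0.455) and antigen presentation lists (Canx 0.378). Bub1b was the 1 limma-voom call among these lists. Of the immune and keratinocyte lists 0 members had reads. Adjusted over the list alone, Xrcc4 was lower, 4 chromatin regulators were lower and 2 higher, 2 signalling genes lower and 1 higher, and 3 hosts of well described circRNAs lower and 2 higher. As a set, 0 of the 6 lists with enough members passed camera (0 at an unadjusted p under 0.05; lowest 0.0575, cell cycle genes), 0 with an estimated correlation (adjusted p 0.988 each) and 0 by fry. For chromatin regulators the median was 0.12 and the mean -0.25, with camera and fry pointing down. For the signalling list they were -0.01 and 0.06, with camera pointing down and fry up, and for hosts of well described circRNAs -0.12 and -0.08, with camera pointing up and fry down.

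Both comparisons share the lower level of the exon 2 circRNA of Zfp609 in the tumour line, and 656 circRNAs could be tested in both. Called higher in both were 4. That of the tRNA synthetase gene Vars (chromosome 17, 35013265 to 35013747) had log2 folds of 2.41 (SE 0.47) in 4T1 and 2.76 (SE 0.55) in B16F10. That of Fto (chromosome 8, 91401807 to 91409841) was 34.5-fold higher in 4T1, with a 95% counting interval of 8.82 to 297, and had a log2 fold of 3.93 (SE 0.53) in B16F10. Those of the nuclear pore gene Nup155 (2.49, SE 0.61, and 2.12, SE 0.57) and of Tulp4 (chromosome 17, 6137211 to 6139156; 0.95, SE 0.30, and 2.17, SE 0.41) were next. Called lower in both were 10, among them Zfp609 and the glycosylation gene Alg12 (log2 folds -2.18, SE 0.33, and -1.75, SE 0.32). Rad23b was at least 26.5-fold lower in 4T1 and 9.82-fold lower in B16F10 (95% counting interval 3.16 to 49.4), and Mpzl1 at least 8.65-fold lower in 4T1, with a log2 fold of -3.48 (SE 0.65) in B16F10. Several of these calls are fragile. In 4T1, that of Nup155 was lost without any 1 library but 4T1 replicate 3 (edgeR adjusted p 0.0513 to 0.0773) and that of Tulp4 without any 1 but 4T1 replicate 2 (0.0936 to 0.208). That of Fto was lost there without 4T1 replicate 3 (0.127) and Eph4-ev replicates 1 (0.0765) and 2 (0.106), and that of Mpzl1 without Eph4-ev replicates 2 (0.0656) and 3 (0.0642). In B16F10, that of Rad23b was lost without any 1 library but Melan-a replicate 2 (0.057 to 0.117), and that of Nup155 without B16F10 replicates 2 (0.148) and 3 (0.152) and Melan-a replicate 3 (0.0784). With all libraries kept, that of Tulp4 in 4T1 was lost with no filter (0.328) and under limma-voom (0.0673). In B16F10, that of Nup155 was lost under DESeq2 (0.0737), with no filter (0.085) and under limma-voom (0.07), that of Rad23b with no filter (0.0588) and under limma-voom (0.12), and that of Vars under limma-voom (0.0601).

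Independent calls would share 1.51 higher and 6.12 lower circRNAs, against the 4 and 10 seen, and neither overlap passed (two-sided Fisher exact p = 0.0569 and 0.108). Single libraries and the choice of test decide this. With all libraries kept, the overlap of higher calls passed with the replicate block (exact p = 0.0329) and that of lower calls with DESeq2 (0.00256). The overlap of higher calls also passed without B16F10 replicates 1 (exact p = 0.000776), 2 (0.0326) and 3 (0.0252) and Melan-a replicates 1 (0.00759) and 3 (0.045), and that of lower calls without B16F10 replicates 1 (0.0252), 2 (0.00533) and 3 (0.00467). Of the circRNAs called in both, 7 were lower in 4T1 and higher in B16F10, and 0 the reverse by edgeR.

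**Figure D4:**
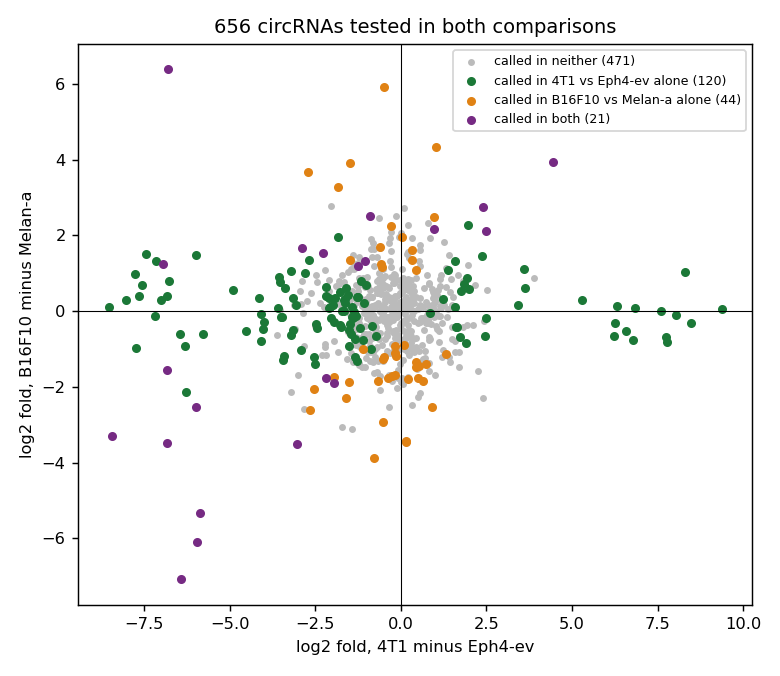
Log2 fold of 4T1 minus Eph4-ev (x axis) against that of B16F10 minus Melan-a (y axis) for the 656 circRNAs tested in both, coloured by where edgeR called them (471 in neither, 120 and 44 in 1 comparison alone, 21 in both), with folds that depend on the prior count where a line has 0 reads. Points spread around 0 on both axes with little common trend.

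Across circRNAs, which are not independent replicates, the folds had a Pearson correlation of 0.0878 (permutation p = 0.0235) and a Spearman correlation of 0.027 (permutation p = 0.492). The fold of tumour line minus non-tumour line differed between the comparisons for 162 of 1403 circRNAs in the edgeR interaction test (366 at an unadjusted p under 0.05). It was more positive in the mammary comparison for 53 and in the melanocyte comparison for 109. Without Eph4-ev replicate 2 the test called 103 in all. These are differences between single pairs of lines, so neither tumour state nor lineage can be told apart from line identity. Met is an example, lower in 4T1 and higher in B16F10 (host difference -5.63, adjusted p = 5.72e-07). Bub1b was lower in 4T1 and not called in B16F10 (log2 fold 0.93, SE 0.39, adjusted p = 0.188), with a host difference of -3.87 (adjusted p = 0.000418). For the exon 2 circRNA of Zfp609 the difference was 0.39 (SE 0.50, adjusted p = 0.69).

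Of the 268 host genes with a called circRNA in the mammary comparison, 39 had 2 or more, and 6 had calls in both directions (Mllt10, Pik3c2a, Pvt1, Rere, Tns3 and Trio). This count was 6 with RLE factors, 3 under DESeq2 or with no filter, 1 with the replicate block, and at most 2 without any 1 library, whichever of the 6 was left out. In the melanocyte comparison 12 of 80 had 2 or more calls, and 0 had calls in both directions by edgeR, by DESeq2, with RLE factors, with no filter, with the replicate block or without any 1 library.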

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

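The tests of the difference between lineages were planned for circRNAs and were added after seeing the data for host genes, and the test of other splits was chosen after the result was seen. Values are the log2 effect (tumour line minus non-tumour line) in the mammary comparison minus that in the melanocyte comparison, from edgeR. Each passed its test of that difference (adjusted p under 0.05). The difference passed for 162 circRNAs. Among 100 splits of the 6 libraries of each lineage, 1 gave as many, the real one, and the highest of the others gave 79. These splits mix tumour and non-tumour libraries, so they set the count against no difference between the lines at all. They cannot decide whether equal effects in both lineages would give as many.

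Only circRNAs named by the rule fixed beforehand are listed here. Those whose effect was more positive in the mammary comparison included those of Pvt1 (0.88), Med13l (1.96), Qk (6.13), Adk (4.57), Vps45 (3.01), Fam160b1 (8.89), Kirrel3os (8.57), Nedd4 (8.38) and Stk39 (6.81). CircRNAs whose effect was more negative there included those of Dtnb (-2.09), Vapa (-2.23), Ptbp3 (-3.59), Bub1b (-4.51), Snx12 (-3.32), Eefsec (-1.91), Eif5b and Rev1 (-4.63), Met (-7.87 and -5.22) and Cntln (-13.35). Where a line has 0 reads the value is fitted, depends on the prior count and is no bound.

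Among host genes named in the text the difference was negative for Ezh2 (-2.68), Asxl2 (-1.78), Whsc1 (-1.71), Bub1b (-3.87), Smad4 (-2.50), Asph (-2.05), Pax3 (-7.14), Ash1l (-2.16) and Met (-5.63), and positive for Qk (3.82), Arid1b (1.97) and Pvt1 (1.18). Pax3 was not among the hosts with enough reads to be tested in the mammary comparison alone, so its value is fitted and is no bound.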

How the results depend on the processing

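Thinning before the tests, limma-voom with quality weights and the host-level interaction were chosen after seeing the data. 0 of the calls of either comparison changed sign in any alternative. In simulated data most 2-fold changes went undetected, with 1.92% recovered in the mammary and 14.5% in the melanocyte circRNA test. The alternative with another pseudocount, planned for tables of normalized values, was not run because counts were given. The cause of the changes below was not tested, except that fewer libraries, fewer rows or fewer reads enter some settings by construction.

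With no filter, 72 circRNAs were higher in 4T1, 41 host genes were higher in B16F10 and 3 hosts had calls both ways. Thinned to equal depth, 109 circRNAs and 97 host genes were lower in 4T1, and the circRNAs found only in Eph4-ev and only in Melan-a were 93 and 24. With a minimum of 1 read the line-only counts were 96 (4T1), 549 (Eph4-ev), 102 (B16F10) and 98 (Melan-a), and with 5 reads 16, 119, 6 and 11. Hosts with calls both ways were 3 under DESeq2 and 1 with the replicate block. The fry test called 3 lists in 4T1 (adjusted p = 0.0484 each). The overlap of higher calls passed with the replicate block (4 circRNAs, Fisher exact p = 0.0329; 0.0329 to 0.166 over the alternatives that keep all libraries) and that of lower calls with DESeq2 (10 circRNAs, p = 0.00256; up to 0.174). With at least 2 reads, a B16F10 library held fewer circRNAs than a Melan-a library (difference -421, exact permutation p = 0.3).

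No pairing by replicate number was seen: correlations of the same number across lines lay between -0.06 and 0.07, and those of other numbers reached 0.107. With counts this sparse, values near these could also arise from paired libraries, so pairing is not excluded. With replicate number as a block, 82 circRNAs were higher and 166 lower in 4T1, and 38 and 40 in B16F10, with 82 and 135 and with 29 and 40 host genes, and the interaction gave 138.

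Leaving out 1 library gave, for 4T1, 30 to 81 circRNAs higher, 42 to 173 lower, 31 to 91 host genes higher, 42 to 170 lower, 0 to 1 lists, 0 to 2 hosts both ways, 62 to 128 circRNAs only in 4T1 and 447 to 598 only in Eph4-ev. For B16F10 it gave 22 to 72 and 20 to 73 circRNAs, 16 to 60 and 13 to 63 host genes, 48 to 92 circRNAs only in B16F10 and 72 to 135 only in Melan-a. Line-only counts rise because fewer libraries must meet the rule. The overlaps were 1 to 4 and 3 to 10 (exact p 0.000776 to 0.564 and 0.00467 to 0.774), and the interaction 103 to 169. The difference in detected circRNAs was -2019 to -1680 in the mammary lines and -110 to 344 in the melanocyte lines, negative without B16F10 replicate 1 (-97.8) and Melan-a replicates 1 (-62.3) and 3 (-110). The difference in junction reads was -37629 to -23102 and -11473 to -7231.

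List directions that turned, with adjusted p, all miss 0.05. Over the settings that leave out 1 library, adjusted p ran from 0.809 to 0.983 for chromatin regulators, 0.834 to 0.983 for the TGF-beta list and 0.774 to 0.983 for hosts of well described circRNAs in 4T1. In B16F10 it ran from 0.0679 to 0.579 for DNA repair genes, 0.739 to 0.998 for the signalling list and 0.871 to 0.998 for hosts of well described circRNAs. In 4T1, chromatin regulators turned under fry (0.188) and without 4T1 replicate 1 (0.955) and Eph4-ev replicates 1 (0.968) and 3 (0.983), the TGF-beta list without 4T1 replicates 2 (0.966) and 3 (0.983) and Eph4-ev replicate 3 (0.983), and hosts of well described circRNAs under fry (0.0744) and without 4T1 replicate 3 (0.983) and Eph4-ev replicates 1 (0.968) and 2 (0.916). In B16F10, DNA repair genes turned without each library (0.487, 0.0679, 0.579, 0.523, 0.109 and 0.303), the signalling list under fry (0.967) and without B16F10 replicates 1 to 3 (0.976, 0.967 and 0.998) and Melan-a replicate 1 (0.894), and hosts of well described circRNAs under fry (0.878), the block (0.977) and without B16F10 replicate 2 (0.967) and Melan-a replicates 1 (0.894) and 2 (0.988). Of uncalled named items in 4T1, the Pvt1 circRNA turned with no filter (-0.20) and without 4T1 replicate 2 (-0.02) or Eph4-ev replicate 1 (-0.0308; up to 0.119 without Eph4-ev replicate 3), that of Gigyf2 under total reads (0.0706) and thinning (0.11), and Myo5a under limma-voom (-0.32) and without 4T1 replicate 3 (-0.69) or Eph4-ev replicate 1 (-0.07; up to 0.726 without 4T1 replicate 2). In B16F10, Pard3 turned without B16F10 replicate 2 (-0.0576; up to 0.757 without B16F10 replicate 3).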

Other observations

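The tests of host concordance, of the blank database columns, of other splits, of depth and single losses for line-only circRNAs, of B16F10 RNA and exchange for Melan-a replicate 2, and both tests of 4T1 replicate 3 were chosen after the result was seen. CircRNAs of 1 host tended to move together. Of 51 host genes with 2 or more called circRNAs in either comparison, 45 had all of them in 1 direction, against 24.4 on average with directions shuffled among the calls (permutation p = 0.0001, the smallest that 10000 shuffles can give). The named circRNAs of Met and of Fto share their start (17487797 and 91401807). A change of the host gene as a whole is a candidate explanation, since linear RNA is not analysed here.

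A pair of hypotheses written before their tests stays open. Whether circRNAs that hold the start of the coding sequence were called more often than others did not pass: 18.1% against 17.1% were called in the mammary comparison (Fisher exact p = 0.698, adjusted 1 over 6 tests) and 8.56% against 11.3% in the melanocyte comparison (p = 0.349, adjusted 0.698). That line-only circRNAs are less often listed in databases could not be tested. The database columns were filled for 13 of the 52 circRNAs found only in 4T1 against 97.8% of its others (Fisher exact p = 3.77e-43) and for 42.4% against 99.1% in B16F10 (p = 1.02e-24), with 100% filled for those only in Eph4-ev and only in Melan-a (p = 1 for each). But 536 circRNAs with blank columns in 1 table carry an identifier in the other, so a blank may only mean that the columns were not filled, and 372 circRNAs with reads in Eph4-ev alone are marked as having no entry.

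CircRNAs found in 1 line only were set against the number that would meet the same rule if every circRNA in the table were equally abundant in both lines. Poisson sampling at the depths of the libraries would give 0.0735 only in 4T1, where 52 were seen, and 0.425 only in B16F10, where 33 were seen, which argues against depth there. It would give 37.1 of the 334 only in Eph4-ev and 11.3 of the 44 only in Melan-a, so depth could account for part of these. The rates of loss seen between replicates at the same level, multiplied over the libraries, would give 7.70 only in 4T1, 208 only in Eph4-ev, 13.2 only in B16F10 and 25.8 only in Melan-a. Independent losses thus stay open for part of each count, the larger part in Eph4-ev and Melan-a. Of the 147 that edgeR called, 0 had a listed neighbour within 10 bp at both ends with reads in the other line. Few such neighbours may be listed at all, since 99.2% of starts and 99.3% of ends lie at annotated exon boundaries in both comparisons. The count was not set against that among other circRNAs, so it cannot decide whether ends were assigned wrongly before listing. The other circRNAs of the hosts of these 147 mostly differed in the same direction, where they had enough reads to be compared. Their median log2 ratio was 1.34 over 77 hosts (95% interval 0.94 to 2.55), so a change of the whole host may contribute. The ratio was above 0 for 81.8% of these hosts, and hosts with too few such reads were left out. Losses that strike several libraries of 1 line together stay open.

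Melan-a replicate 2 lay towards B16F10. Over the 145 circRNAs called without it, its median position was 0.354 on a scale from the other Melan-a libraries (0) to B16F10 (1), against 0 and -0.0621 for replicates 1 and 3 treated likewise. The Met level of replicate 2 would need a share of 12.8% of B16F10 RNA in the library. That share is argued against by 9 circRNAs of B16F10 that replicates 1 and 3 lack. It would give 30.5 of their reads, where replicate 2 held 7 (95% Poisson interval 2.81 to 14.4). The interval covers counting error only, and a smaller share stays open. Exchange with a B16F10 library is argued against by 7 circRNAs with 0 reads in B16F10 and at least 10 in each of replicates 1 and 3, chosen without regard to replicate 2. It held 5 of them, at 0.751 of their summed level there (0.362 without the most abundant, that of Col28a1), where each B16F10 library has 0 reads. Depth is argued against by a position of 0.337 after thinning. No biological explanation was tested, and a different state of that culture stays open.

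4T1 replicate 3 held 592 circRNAs with 5 or more reads that both other 4T1 libraries lack (26.5% of 2233), against 3.65% to 15.9% in the other libraries. Poisson sampling at the depths of the libraries would leave 12.1 so. Every other library also held more than such sampling would leave, such as 244 against 0.0376 in Eph4-ev replicate 2 and 254 against 0.203 in Melan-a replicate 2. The value of 12.1 thus does not set replicate 3 apart and cannot decide what part its depth plays. The share of detected circRNAs with 1 read in 4T1 replicate 3 was 9.35%, against at least 18.7% in each of the Eph4-ev libraries thinned to its depth. Thinned to 15572 reads, however, its share was 27.8%, between those of 4T1 replicates 2 (27.3%) and 1 (29.7%), against 38.9% to 41.3% in Eph4-ev. A low share is thus common to the 4T1 libraries and does not set replicate 3 apart, and few starting molecules amplified to many reads stay open. No biological explanation was tested.

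Other splits of the 6 libraries of a comparison number 10 with the real one, too few for a share under 0.05. Each other split mixes tumour and non-tumour libraries in both groups, so the difference between the lines adds to the spread within groups. Few circRNA and host calls in them are thus built in, and no conclusion is drawn from them. For circRNAs the real split called 325 (mammary) and 95 (melanocyte), and the highest other 0 and 1, with 1 split as large in each, the real one. For host genes it called 265 and 64, and the highest other 0 and 1, again with 1 as large. For gene lists it called 0 in both, the highest other 2, and 10 splits gave as many.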
